A study of Mus musculus with 25 samples.

How the data were processed

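The series holds 25 mouse samples, of which 16 had a file that could be used: 8 ATAC-seq libraries (J1 ES cells, TS cells, and ES-derived lines overexpressing Cdx2, Arid3a or Gata3, each in ES+ and TS+ medium) and 8 ChIP-seq libraries of the same groups. The 8 RNA-seq samples and the mock pull-down from cells with the biotin ligase alone had no file here and were not analysed here. Each group held 1 library per assay, so no value has a spread between replicates and no test between single libraries was made. The media were also compared with the 3 lines as pairs, by an exact sign-flip test.

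ATAC-seq peaks were called by the authors with MACS 2.1.0.20140616 per the file headers, on reads of combined files, without a control, at a q value of 0.05, with an effective genome size of 1870000000 bp, 1 tag kept per position and a background range of 10000 bp. The pileup of each peak is the signal at its summit, deposited by the authors as a fragment count without scaling between libraries. The fold enrichment deposited by the authors is the ratio of the pileup to the local background. The −log10 p and −log10 q columns deposited by the authors are the scores of that caller. ChIP-seq summits were called by the authors with MACS2, version and control not given in the sources used here, and their deposited score was read as a −log10 q value. The labels give mm9 as the genome build, and the positions were used as deposited. The lists differ in their lowest score (15.1 for Arid3a in ES+, 10.001 for Gata3 in ES+, 5.004 for Gata3 in TS+ and 1.30 to 1.34 for the other streptavidin lists). Depth after filtering was read from the headers of the ATAC-seq files, from 38056559 to 51977223 tags. The depth of the ChIP-seq libraries is unknown.

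Peaks and summits on chromosomes 1 to 19, X and Y were used. Peaks of ES and TS cells that overlapped by at least 1 bp were joined into regions, and each region was classed as ES-only, shared or TS-only. A factor line was counted as having a peak at a region when they overlapped by at least 1 bp. Summits were called shared within 250 bp, and a summit was called inside a peak when it lay between its start and end. Chance overlap came from 100 circular shifts of 1 list along each chromosome by at least 1000000 bp. Shares carry exact (Clopper-Pearson) 95% binomial intervals. Intervals of differences use the normal approximation, for paired shares where the same regions were compared. All of them cover counting error only, and neighbouring regions are not independent. Peak scores and folds are compared within a list, except that a common lowest score of 15 was also applied to all ChIP-seq lists, whose scores depend on depth. Because list lengths differed, the shares were also computed from the 40117 highest-scoring peaks of each ATAC-seq list and the 5383 highest summits of each streptavidin list. Regions and summits named by position were, by a fixed rule, the 3 highest-scoring of each region class and of each ChIP-seq list.

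The comparisons, the overlap and window rules, the naming rule and most alternatives were set before the data were examined. The alternatives were overlap of 0.5 of the shorter peak, windows of 100 and 500 bp, the upper part of each list by score, equal numbers, autosomes only, and leaving out regions of the ES cell ChIP-seq list. The common lowest score of 15, the grouping of TS-only regions by score, the counts of regions that separate the media, the pairing by line and equal line lists on the regions of all peaks were added afterwards. Comparisons of gene lists, overexpressed genes, motifs and genomic distribution were planned and not run. The RNA-seq files and an mm9 sequence and annotation were lacking, and the available gene tables are for another build. The overlap, class, summit and split code was tested on simulated data, where 19.9% planted overlap over 40117 peaks gave 19.9% and 10288 planted shared regions gave 10288. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.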

Results

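Chromatin accessibility and transcription factor occupancy were profiled in mouse embryonic stem (ES) cells of the J1 line, in ES-derived lines that overexpress Cdx2, Arid3a or Gata3, and in trophoblast stem (TS) cells, which the labels call trophoblast stem-like. Cdx2 is a caudal-type homeobox factor and Gata3 a zinc finger factor, both known from trophectoderm, the outer layer of the blastocyst that gives rise to the placenta. Arid3a binds DNA through an AT-rich interaction domain and is also known from early trophoblast. ES cells normally contribute to the embryo proper, and the labels describe the factor lines as cells in conversion toward a TS-like state. Each factor line was kept in ES+ medium and in TS+ medium. There were 8 ATAC-seq peak lists (1 for ES cells, 6 for factor lines, 1 for TS cells) and 8 ChIP-seq summit lists, with 1 library in each of these groups. ATAC-seq marks DNA open to a transposase, and ChIP-seq marks DNA bound by a protein. The factor lines were pulled down with streptavidin beads, and ES and TS cells with an Arid3a antibody. The deposited name of the ES cell ChIP-seq list calls it a mock, so its 456 summits are given as those of the library labelled Arid3a antibody in ES cells. With no replicate there was no test between single libraries, and the 95% intervals, exact binomial for shares and normal for differences, cover counting error only. ATAC-seq depth after filtering was 42843924 tags in ES cells and 43084383 in TS cells. In the Cdx2, Arid3a and Gata3 lines it was 51861564, 51977223 and 38056559 tags in ES+ and 43667523, 49888217 and 38967217 in TS+. ChIP-seq depth is unknown.

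The accessible regions of ES and TS cells, the start and end points of the conversion, differed widely. ES cells had 85766 peaks covering 28.4 Mb and TS cells 40117 peaks covering 11.7 Mb. Joined where they overlapped by at least 1 bp, the lists gave 59532 ES-only regions, 25817 shared regions and 12658 TS-only regions. An ES cell peak overlapped 68.4% (67.99 to 68.90) of TS cell peaks, against a mean of 2.05% when peaks were moved by random distances along their chromosomes. A TS cell peak overlapped 30.6% (30.3 to 30.9) of ES cell peaks. Within each list, shared peaks were stronger than the rest. Their median fold enrichment over local background was 5.99 against 4.26 for ES-only peaks in the ES cell list, and 5.09 against 4.53 for TS-only peaks in the TS cell list. Peaks were also spread differently over chromosomes: chromosome 1 held 10.3% of ES cell peaks, 9.51% to 10.7% of the peaks of the factor lines and 7.74% of TS cell peaks.

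**Figure D1:**
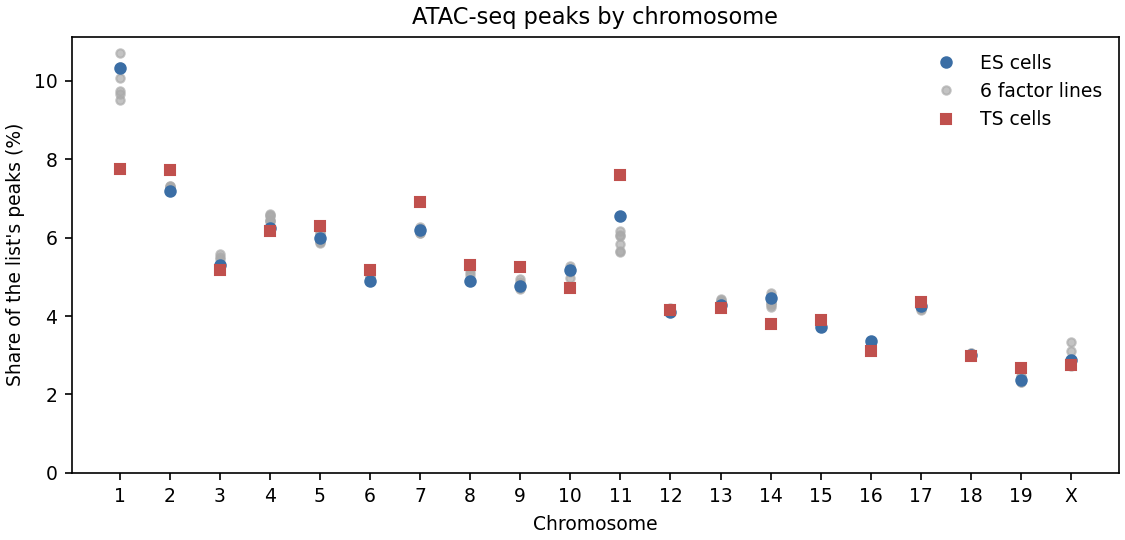
Share of the peaks of each ATAC-seq list on each main chromosome, in percent on the vertical axis, for ES cells, TS cells and the 6 factor lines. Chromosome 1 holds 10.3% of peaks in ES cells and 7.74% in TS cells.

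The highest-scoring regions of each class were followed in the factor lines (mm9 coordinates, no gene annotation of this build used here). They need not stand for their class. The top ES-only region, on chromosome 1 from 148170058 to 148170537, had a −log10 q of 77.3 and a 16.7-fold enrichment. It had a peak in all 6 factor lines and a summit in 5 of the 6 streptavidin lists, and also one in the ES cell list that the deposited name calls a mock. The next ES-only regions lay on chromosome 4 from 17019141 to 17019589 (19.6-fold) and on chromosome 3 from 73511799 to 73512362 (19.8-fold). Both also had a peak in all 6 lines. The former held summits of Cdx2 in ES+ and Arid3a in TS+, and the latter a summit of Arid3a in ES+. The top shared regions lay on chromosome 12 from 3109844 to 3110130 and from 98299603 to 98300037, and on chromosome 9 from 35112768 to 35113208. Their −log10 q values were 244, 243 and 223, and none of these regions held a summit of any ChIP-seq list, although no list of artefact-prone regions was used here. The top TS-only region, on chromosome 11 from 12275000 to 12275290, was 15.2-fold enriched in TS cells and had a peak in none of the 6 lines. The second, on chromosome 9 from 24748294 to 24748790 (12.7-fold), had a peak in the Cdx2 line in both media and in the Arid3a line in TS+, and held a Gata3 summit in TS+. The third, on chromosome 5 from 151799144 to 151799475 (12.6-fold), had no peak in any line but also held a Gata3 summit in TS+.

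The factor lines were compared with ES and TS cells to see how far each had moved from the one accessible state to the other. All lines kept far more ES-only regions than they gained TS-only regions. A TS-only region had a peak in 19.98% of cases (19.3 to 20.7) in the Cdx2 line in ES+, 12.3% (11.7 to 12.8) in the Arid3a line in ES+ and 12.3% (11.7 to 12.9) in the Gata3 line in ES+. In TS+ the shares were 13.2% (12.6 to 13.8) with Cdx2, 18.03% (17.4 to 18.7) with Arid3a and 5.04% (4.67 to 5.44) with Gata3. At least 1 line had a peak at 31.0% (30.2 to 31.9) of the TS-only regions, all 6 lines at 1.45%, and no line at 69.0%. ES-only regions kept a peak in 76.3%, 63.3% and 64.7% of cases in the Cdx2, Arid3a and Gata3 lines in ES+, and in 60.1%, 68.04% and 32.6% in TS+. All 6 lines kept 26.7% (26.3 to 27.0) of the ES-only regions, and 12.2% had a peak in no line.

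**Figure D2:**
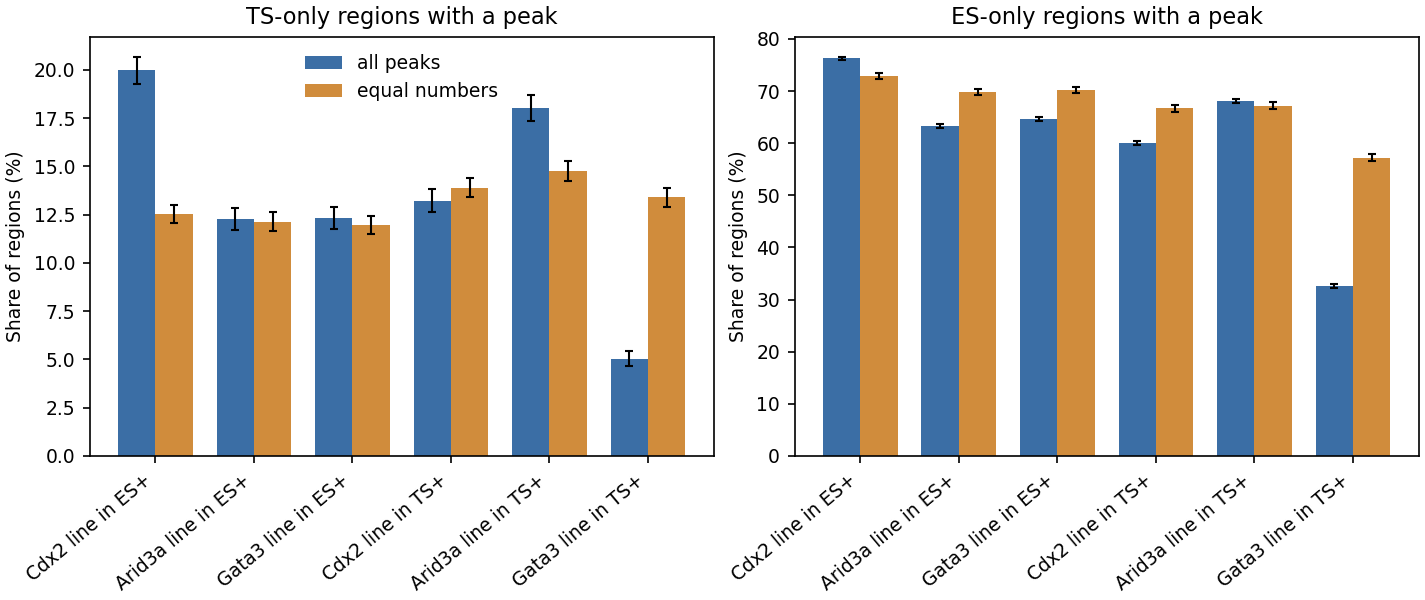
Share of TS-only regions (left) and ES-only regions (right) with a peak in each factor line, in percent, with exact 95% binomial intervals as error bars. Blue bars use all peaks and orange bars the same number of top peaks from every list: the TS-only shares run from 5.04% to 19.98% with all peaks and from 12.0% to 14.8% with equal numbers. Orange bars use regions defined again (18452 TS-only regions, against 12658 for blue), so the colours do not compare the same regions. On the 12658 regions, equal line lists gave 1.93% to 3.98%.

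Shared regions were kept in 94.7% to 98.3% of cases in 5 of the lines and in 83.6% (83.2 to 84.1) in the Gata3 line in TS+. Retention of ES-only regions rose with their score in ES cells. In the strongest of 5 groups of equal size it was 96.9% to 99.4% in the same 5 lines and 79.1% (78.4 to 79.9) in the Gata3 line in TS+, and in the weakest group 27.0% to 46.6% and 8.15%. Gain of TS-only regions did not follow the TS score: in the Cdx2 line in ES+ the weakest group gained peaks in 20.4% and the strongest in 20.1% of cases. In every line, peaks that lay outside ES cell peaks were TS cell peaks more often than the ES cell peaks that the line lacked. These shares were 7.41% against 3.33% in the Cdx2 line in ES+, and 13.03% against 9.97% in the Gata3 line in TS+. Peaks found in neither ES nor TS cells made up 9.18% of the list in the Gata3 line in TS+ and 18.1% to 29.0% in the others with all peaks, and 12.7% to 15.7% in all 6 lines from equal numbers. List lengths ran from 49211 peaks in the Gata3 line in TS+ to 101353 in the Cdx2 line in ES+, so shares were also taken from the same number of top peaks per list, with the region classes defined again. TS-only shares then moved to 12.5% in the Cdx2 line in ES+ and 13.4% in the Gata3 line in TS+. Of the 18452 TS-only regions so defined, 31.4% (30.7 to 32.1) overlapped a weaker ES cell peak. On the 12658 TS-only regions of all peaks, equal line lists gave 1.93% to 2.35% in ES+ and 3.34% to 3.98% in TS+. ES-only shares from equal numbers were 72.9%, 69.8% and 70.2% in ES+ and 66.7%, 67.2% and 57.2% in TS+. On the 59532 ES-only regions of all peaks they were 33.2%, 31.8% and 31.8% in ES+ and 30.8%, 31.0% and 26.1% in TS+.

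The effect of the medium was opposite in sign between factors with all peaks and alike between them with equal numbers. With all peaks, the TS+ minus ES+ difference in TS-only regions was -6.76 percentage points (-7.44 to -6.08) for Cdx2, 5.78 (5.11 to 6.44) for Arid3a and -7.27 (-7.86 to -6.68) for Gata3. With equal numbers it was 1.35 points (0.847 to 1.86), 2.63 (2.12 to 3.14) and 1.41 (0.874 to 1.95), above 0 for each factor. ES-only regions differed by -16.2 points for Cdx2, 4.73 for Arid3a and -32.0 for Gata3 with all peaks. With equal numbers the ES-only differences were -6.23 (-6.91 to -5.55), -2.61 (-3.33 to -1.90) and -13.0 (-13.8 to -12.3), below 0 for each factor. On the regions of all peaks, equal line lists gave 1.26, 2.05 and 1.31 points for TS-only and -2.40, -0.845 and -5.79 for ES-only regions. With the 3 lines as pairs, an exact two-sided sign-flip test gave p = 0.5 for both classes with all peaks and p = 0.25 with equal numbers, the smallest that 3 pairs can give.

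Some regions separated the media in all 3 lines. In all 3 ES+ lists and none of the TS+ lists there were 3903 regions, of which 56.8% (55.2 to 58.4) had an ES cell peak and 7.81% (6.99 to 8.70) a TS cell peak. In all 3 TS+ lists and none of the ES+ lists there were 621 regions, of which 22.2% (19.01 to 25.7) had an ES cell peak and 12.6% (10.1 to 15.4) a TS cell peak. With equal numbers these sets held 1579 and 1166 regions, of which 55.9% and 22.6% had an ES cell peak and 17.7% and 23.7% a TS cell peak. Occupancy of each factor followed the medium. ES+ summits of Cdx2, Arid3a and Gata3 lay in 11.3%, 16.8% and 9.84% of the regions found in ES+ alone and in 4.03%, 4.83% and 1.77% of those found in TS+ alone. TS+ summits lay in 1.77%, 6.30% and 3.13% of the former and in 5.31%, 17.9% and 7.41% of the latter. From equal numbers of peaks the ES+ summits lay in 21.9%, 32.4% and 21.6% of the former and in 7.55%, 9.18% and 5.92% of the latter. The TS+ summits lay in 4.56%, 16.02% and 7.28% of the former and in 7.80%, 24.9% and 9.69% of the latter, a smaller contrast than with all peaks.

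Pairwise similarity placed all factor lines closer to ES cells than to TS cells. The Jaccard index (shared over total covered bp) of ES and TS cells was 0.261. Against ES cells the lines reached 0.580 to 0.603, except the Gata3 line in TS+ at 0.429. Against TS cells the lines reached 0.241 to 0.282, and the Gata3 line in TS+ 0.349. With equal numbers, the Gata3 line in TS+ still had the lowest index with ES cells, 0.514, and the highest with TS cells, 0.359. The other 5 lines were at 0.635 to 0.669 with ES cells and 0.312 to 0.330 with TS cells. Equal numbers of peaks do not equalise covered bp. With all peaks the Gata3 line in TS+ covered 14.5 Mb, against 26.7 to 34.4 Mb in the other lines. By counts from equal lists it had a peak at 53.5% of TS cell peaks, the lowest of the 6 lines, against 55.2% to 57.0%. Of its own peaks 53.0% overlapped a TS cell peak, against 51.2% to 52.2% in the other lines.

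**Figure D3:**
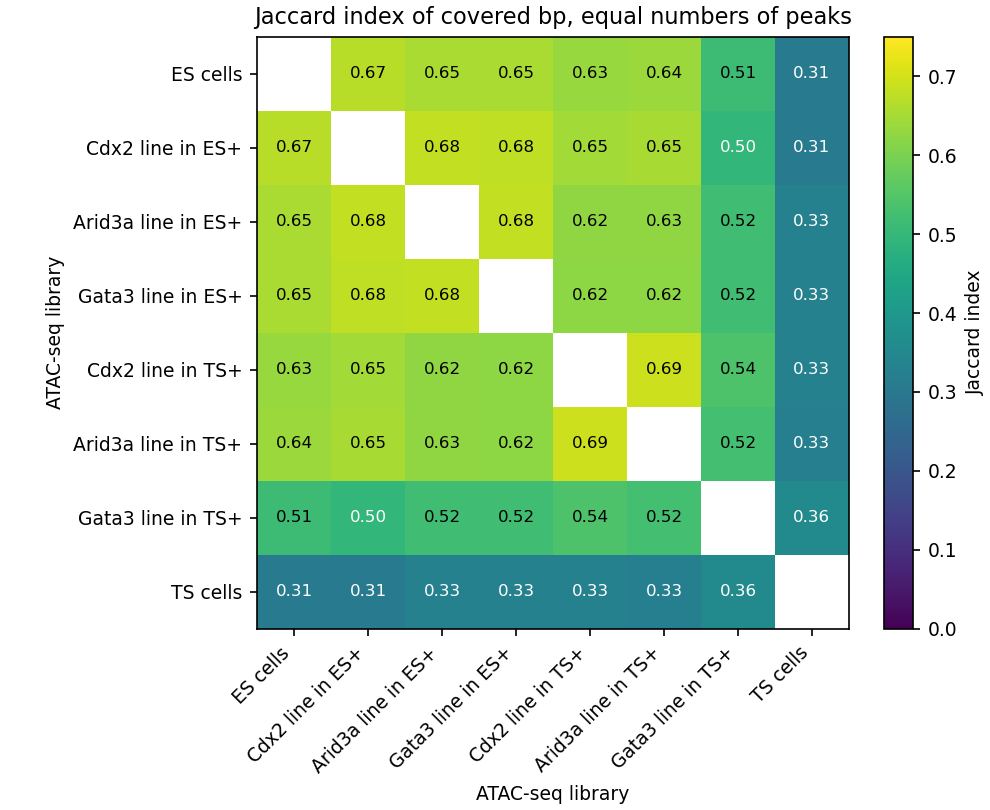
Jaccard index of covered bp between the 8 ATAC-seq libraries, on both axes, from the same number of top peaks per list. TS cells share the lowest values with every other library (0.313 with ES cells). Among the lines, the Gata3 line in TS+ has the highest index with TS cells (0.359) and the lowest with ES cells (0.514). Equal numbers of peaks do not equalise covered bp.

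ChIP-seq lists were compared to see how far the factors occupied the same sites. Summits numbered 13861 for Cdx2, 19479 for Arid3a and 18129 for Gata3 in ES+, and 5383, 15933 and 11270 in TS+. Summits within 250 bp were called shared, and randomly moved streptavidin lists shared at most 0.613% in any draw. In ES+, 39.7% (38.9 to 40.5) of Cdx2 summits had an Arid3a summit and 40.1% (39.3 to 40.9) a Gata3 summit, while 23.2% (22.6 to 23.8) of Gata3 summits had an Arid3a summit. In TS+ the same shares were 60.7% (59.4 to 62.0), 41.2% (39.9 to 42.5) and 42.5% (41.6 to 43.4). The lists were deposited at different lowest scores, 15.1 for Arid3a in ES+, 10.001 for Gata3 in ES+, 5.004 for Gata3 in TS+ and about 1.3 for the others. At a common lowest score of 15, the Cdx2 share with Arid3a was 70.4% in ES+ and 46.8% in TS+, and the Gata3 share with Arid3a was 25.7% and 13.9%. That score left 19479 Arid3a summits in ES+ and 1622 in TS+, so the lists still differed in length between media. With equal numbers of summits the direction was the opposite. The Cdx2 share with Arid3a was then 31.2% in ES+ and 34.8% in TS+, and the Gata3 share with Arid3a 11.4% and 25.1%.

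Each factor kept many of its sites between media. Of the TS+ summits, 60.8% (59.5 to 62.1) of Cdx2, 44.5% (43.8 to 45.3) of Arid3a and 56.3% (55.4 to 57.3) of Gata3 had a summit of the same factor in ES+. In the other direction the shares were 23.7%, 36.3% and 34.9%. From equal numbers of summits, the TS+ shares were 38.5% for Cdx2, 41.0% for Arid3a and 43.3% for Gata3. At a common lowest score of 15 the order changed, to 71.2% for Cdx2, 84.8% for Arid3a and 79.7% for Gata3. At that score 312, 1622 and 1402 summits in TS+ were set against 931, 19479 and 9964 in ES+. The ES+ lists thus differed widely in length, so the order cannot be read as that of the factors. At equal numbers each factor in TS+ met its own ES+ sites more often than the sites of any other factor. The closest other list reached 34.8% for Cdx2 (Arid3a in TS+), 34.6% for Arid3a (Cdx2 in TS+) and 26.2% for Gata3 (Cdx2 in ES+). For Cdx2 the margin was not clear in other settings. As listed it was 60.8% against 60.7% for Arid3a in TS+. At a lowest score of 15 it was 71.2% (65.8 to 76.1) against 68.9% (63.5 to 74.0) for Arid3a in ES+.

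Most of the highest summits recurred between media. For Cdx2 the top summit was on chromosome 4 at 108874545 in ES+ (−log10 q 142) and at 108874544 in TS+ (99.1), inside a peak of all 8 ATAC-seq lists. The next in ES+, on chromosome 4 at 117006195 and chromosome 14 at 33800049, lay in no ATAC-seq peak of any library. The latter was also the second in TS+, at 33800059. The third Cdx2 summit in TS+, on chromosome 1 at 11320455, was shared by all 6 streptavidin lists. For Arid3a the top pair lay on chromosome 13 at 65592947 and 65728567 in ES+ (581 and 519) and at 65592954 and 65728614 in TS+ (159 and 121). The third was on chromosome 13 at 66812117 in ES+ and on chromosome 16 at 18460180 in TS+. All of these Arid3a sites had a summit in each of the 5 other streptavidin lists and a peak in ES cells. Those on chromosome 13 also had a summit in the ES cell list that the deposited name calls a mock. For Gata3 in ES+ the top summits were on chromosome 5 at 138721632 (169), chromosome 1 at 52170736 (156) and chromosome 11 at 77321739 (152), all inside ES and TS cell peaks and with a Gata3 summit in TS+. In TS+ they were on chromosome 17 at 67639881 (95.8), in no ATAC-seq peak and near a summit of the ES cell list but of no other streptavidin list, and on chromosome 11 at 109334607 (86.2) and 95275152 (78.2), inside peaks of all 8 ATAC-seq lists and each with a Gata3 summit in ES+.

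Factor summits were set against accessibility to ask whether the factors sat at DNA already open in ES cells. ES cell peaks held 65.4% (64.6 to 66.2) of Cdx2, 44.2% (43.5 to 44.9) of Arid3a and 71.2% (70.5 to 71.9) of Gata3 summits in ES+. In TS+ they held 65.3% (64.0 to 66.6), 62.8% (62.0 to 63.5) and 74.7% (73.9 to 75.5), against about 1.1% for randomly moved summits. Arid3a in ES+ had the lowest share, by a margin that depended on how the lists were matched. Among the 5383 highest summits of each list it was 63.1% (61.8 to 64.4), against 65.3% to 84.3% in the others. At a common lowest score of 15, which removes none of its summits, it was 44.2% against 73.1% to 88.4%. The shares also depended on the length of the ES cell list, whose 40117 highest peaks held 30.6% to 55.7% of summits in ES+ and 46.5% to 58.1% in TS+. Summits in peaks of TS cells but not ES cells were rare for the factor lines, from 2.16% (1.9555 to 2.38) for Gata3 in ES+ to 3.64% (3.33 to 3.96) for Cdx2 in ES+. No random value was computed for this set, and all TS cell peaks covered 11.7 Mb against 28.4 Mb for ES cell peaks. Among summits outside ES cell peaks, the line's own ATAC-seq list held 34.0% for Cdx2, 15.8% for Arid3a and 24.2% for Gata3 in ES+, and 27.7%, 32.8% and 8.57% in TS+. They depended on list length: the longest list, the Cdx2 line in ES+, held 33.5% of such Gata3 summits and 21.6% of such Arid3a summits in ES+, more than their own lines. The own-line shares from equal numbers of peaks were 5.27% to 7.41% in ES+ and 6.54% to 11.99% in TS+. Even so, the own line held the highest share within its medium only for Arid3a in ES+. Of such Gata3 summits in TS+ the own line held 6.54%, against 10.7% in the Arid3a line and 9.70% in the Cdx2 line. Of such Arid3a summits in TS+ it held 10.9%, against 12.0% in the Cdx2 line.

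**Figure D4:**
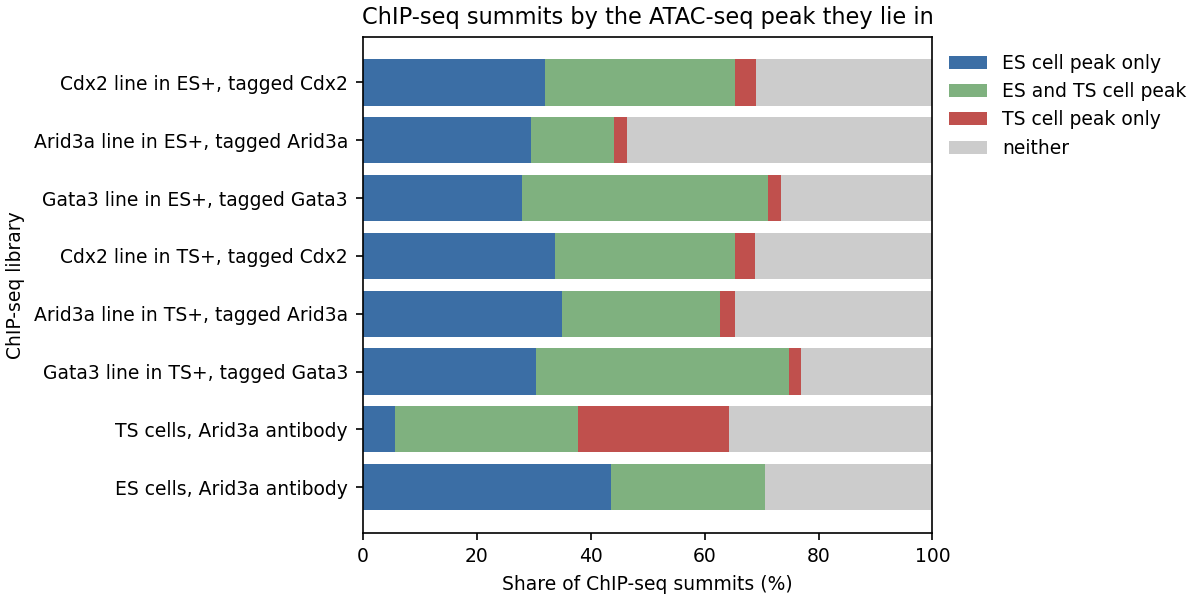
Share of the summits of each ChIP-seq library, in percent on the horizontal axis, that lie in a peak of ES cells alone, of ES and TS cells, of TS cells alone or of neither. Peaks of TS cells alone hold 26.5% of the Arid3a antibody summits in TS cells and 2.16% to 3.64% of the summits of the factor lines.

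Occupancy also differed between region classes. Shared regions held a summit most often for every streptavidin list. They were also longer, with a median of 468 bp against 205 bp for ES-only and 177 bp for TS-only regions. The shares were not scaled by length. Gata3 in ES+ had a summit in 33.4% (32.8 to 33.9) of shared, 7.17% of ES-only and 1.74% of TS-only regions. Cdx2 in ES+ had one in 19.7%, 6.70% and 2.95%, and Arid3a in ES+ in 13.6%, 8.75% and 2.46%. In TS+ the shared regions were at 7.55% for Cdx2, 19.3% for Arid3a and 20.6% for Gata3, and the TS-only regions at 1.06%, 2.25% and 1.23%. No factor had a summit in 94.0% of TS-only regions in ES+ and in 96.3% in TS+.

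The few TS-only regions that held a factor's summit were accessible in that factor's line more often than the rest. In ES+ this was 49.5% (44.3 to 54.7) of 374 regions against 19.1% for Cdx2, 43.1% (37.5 to 48.8) of 311 against 11.5% for Arid3a, and 54.1% of 220 against 11.6% for Gata3. In TS+ the differences were 31.9 percentage points for Cdx2, 53.3 for Arid3a and 24.1 for Gata3. With equal numbers of line peaks the differences on the same regions were smaller, at 2.81, 6.92 and 9.498 points in ES+ and 11.4, 17.1 and 20.6 in TS+, since shorter lists lower every share. The ratio of the share with to that without a summit was 2.59, 3.75 and 4.68 in ES+ and 3.48, 4.17 and 6.08 in TS+ with all peaks, and 2.24, 4.94, 6.09, 4.28, 5.76 and 7.68 with equal numbers. The link was not particular to TS-only regions. ES-only regions with a factor's summit also had a peak in its line more often, in each of 3 groups by ES score. The weakest group was at 84.7% against 52.5% for Cdx2 in ES+, and the strongest at 76.3% against 64.0% for Gata3 in TS+. With all peaks, lines of other factors also had a peak at bound regions more often than at the rest, and which line ranked highest depended on list length. Regions with a Gata3 summit in TS+ had a peak in 77.6% of cases in the Arid3a line, 60.9% in the Cdx2 line and 28.8% in the Gata3 line with all peaks. From equal numbers the shares were 17.3% (11.7 to 24.2), 20.5% (14.5 to 27.7) and 23.7% (17.3 to 31.2), with overlapping intervals. They cover the same 156 regions, so the overlap of these intervals does not tell whether the lines differ. Within a medium, from equal numbers, the own line ranked first alone only for Gata3 in TS+. For Gata3 in ES+ it tied with the Arid3a line, at 11.4% in both. Regions with an Arid3a summit in ES+ were at 8.68% in the Arid3a line and 9.65% in the Cdx2 line. Those with a Cdx2 summit in TS+ were at 14.9% in the Cdx2 line and 20.1% in the Gata3 line. Regions with a Cdx2 summit in ES+ were at 5.08% in the Cdx2 line, 6.68% in the Arid3a line and 5.88% in the Gata3 line. Those with an Arid3a summit in TS+ were at 20.7% in the Arid3a line, 23.5% in the Cdx2 line and 21.8% in the Gata3 line.

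Arid3a in TS cells, measured with an antibody, shared part of its places with the streptavidin-captured Arid3a of the factor lines. Of its 11797 summits, 58.7% (57.8 to 59.6) lay in a TS cell peak and 37.9% in an ES cell peak, and 26.5% (25.7 to 27.3) lay in peaks of TS cells alone. It occupied 22.1% (21.4 to 22.8) of TS-only regions, 15.9% (15.4 to 16.3) of shared regions and 0.885% (0.812 to 0.964) of ES-only regions. An Arid3a summit of the factor line lay within 250 bp of 16.2% (15.6 to 16.9) of its summits in ES+ and 17.7% (16.998 to 18.4) in TS+, against 0.394% and 0.309% for randomly moved summits. At a common lowest score of 15 these shares were 25.7% in ES+ and 6.05% in TS+, with 19479 and 1622 Arid3a summits of the line left. Gata3, as listed, reached 16.9% (16.2 to 17.5) in ES+, an interval that overlaps that of Arid3a in the same medium. At equal streptavidin summit numbers, Arid3a shares were 6.04% in ES+ and 7.66% in TS+, and those of Cdx2 and Gata3 6.39% to 7.65%. The top Arid3a antibody summits in TS cells were on chromosome 15 at 72399147 (−log10 q 300), chromosome 7 at 6362947 (297) and chromosome 19 at 4989173 (262). Only the one on chromosome 7 lay in a TS cell peak, and all of them had a summit of the ES cell list nearby. Of the 456 summits of that ES cell list, 67.8% (63.3 to 72.0) had an Arid3a summit of the line in ES+ and 48.0% (43.4 to 52.7) a Cdx2 summit. With equal numbers of streptavidin summits the shares were 53.7% and 34.6%. At a lowest score of 15 they were 33.3% and 4.76% of 42 summits. The top summits of the ES cell list were on chromosome 2 at 69193659 (94.6), chromosome 12 at 25110031 (43.9) and chromosome X at 8191637 (40.3). None of its summits lay in a TS-only region, which allows a share of up to 0.029% of the 12658 regions.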

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

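Of the tests below, those of sequencing depth and of the loss of ES-only regions were chosen after the result was seen, and the test within groups of regions of like ES score was set before it.

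The response to medium went in opposite directions between factors, and this difference between factors was not tested, since each group had 1 library. The number of ATAC-seq peaks in TS+ minus ES+ was -24551 for Cdx2, 12122 for Arid3a and -31136 for Gata3. The difference in the percent of TS-only regions with a peak was -6.76 for Cdx2, 5.78 for Arid3a and -7.27 for Gata3. For ES-only regions it was -16.2, 4.73 and -32.0. With equal numbers of peaks the signs were alike among the factors, at 1.35, 2.63 and 1.41 for TS-only regions and -6.23, -2.61 and -13.0 for ES-only regions.

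The Gata3 line had 80347 peaks in ES+ and 49211 in TS+, the largest drop of the 3 lines. Lower sequencing depth is argued against, since the ratio of tags after filtering was 1.02 in TS+ over ES+. Loss of weak peaks whatever the region class stays open. Within 10 groups of like ES score and with equal numbers of peaks, the odds ratio of keeping shared against ES-only regions was 4.12 (3.88 to 4.37), and its interval overlaps that of the Arid3a line in TS+, 3.77 (3.52 to 4.03). A loss of ES-only regions in TS+ medium, the biological explanation that the design gives, may contribute: with equal numbers of peaks the difference was -13.0 percentage points, against -6.23 for Cdx2 and -2.61 for Arid3a. Library quality and a change of the cells cannot be told apart here, because there was 1 library for each line and medium.

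Signals outside the compared regions were also found. Peaks on unplaced chromosome Y sequence numbered 363 in ES cells, 187 to 352 in the factor lines and 20 in TS cells. Mitochondrial summits numbered 11 in the Arid3a antibody list of TS cells, 3 in that of ES cells and 0 in the streptavidin lists. The highest peak number in the names of the summits was 173658 for Arid3a in ES+, 53993 for Gata3 in ES+ and 20342 for Gata3 in TS+, above the 19479, 18129 and 11270 summits used. These are the lists with the highest lowest scores, 15.1, 10.001 and 5.004. In every other ChIP-seq list 100% of the numbers are present. Beyond that, no explanation of the chromosome Y, mitochondrial and peak number signals was tested.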

How the results depend on the processing

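The common lowest score of 15 was chosen after the data were seen, as were the grouping of TS-only regions by score, the 3-against-3 splits of the lists, the pairing of media by line, and equal line lists on the regions of all peaks. The other alternatives were planned. Paired by line, the 3 media differences cannot give an exact two-sided p below 0.25. Of 218 values under alternatives, 86 stayed within the interval of the reported value (or within 1.5 times a count), 129 moved beyond it and 3 changed sign. Autosomes alone left the 6 values tried within their intervals, and leaving out regions of the ES cell ChIP-seq list left 42 of 44. Values below are in the order Cdx2, Arid3a, Gata3, for ES+ and then TS+, unless stated otherwise.

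With equal numbers of peaks, the TS+ minus ES+ difference in TS-only regions reversed to 1.35 for Cdx2 and 1.41 for Gata3 and moved to 2.63 for Arid3a. The difference in ES-only regions reversed to -2.61 for Arid3a and moved to -6.23 for Cdx2 and -13.0 for Gata3. ES-only regions numbered 19889, close to the TS-only number by construction. TS-only regions with a peak became 12.5% (Cdx2 in ES+), 13.9% (Cdx2 in TS+), 14.8% (Arid3a in TS+) and 13.4% (Gata3 in TS+). The excess of accessibility at bound TS-only regions became 21.2, 23.1 and 29.3 points in ES+ and 31.2 for Arid3a in TS+ with regions defined again, and 2.81, 6.92, 9.498, 11.4, 17.1 and 20.6 points on the regions of all peaks. Summits inside ES cell peaks became 48.9%, 30.6%, 55.7%, 49.5%, 46.5% and 58.1%. The Jaccard index of ES and TS cells became 0.313. The equal lists drop the weaker peaks of the longer lists by construction. Beyond that, the cause was not tested.

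In the upper part of each list by score, the ES-only, shared and TS-only regions numbered 28831, 13954 and 5895, which follows from the smaller lists. TS-only regions with a peak became 11.6% (Arid3a in ES+), 12.6% (Cdx2 in TS+) and 6.04% (Gata3 in TS+). The medium difference in TS-only regions became -5.92 for Gata3, and in ES-only regions -19.3, 5.55 and -35.4. The excess at bound TS-only regions became 16.4 points for Gata3 in TS+. With 0.5 of the shorter peak covered, TS-only regions with a peak became 13.002% (Arid3a in ES+) and 13.8% (Cdx2 in TS+), and the difference in ES-only regions -15.6 for Cdx2 and -30.6 for Gata3. The cause was not tested.

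Overlap between factors is given as Cdx2 with Arid3a, Cdx2 with Gata3 and Gata3 with Arid3a. It became 31.3%, 31.8%, 17.4%, 48.7%, 33.7% and 35.1% within 100 bp, and 42.5%, 43.3%, 25.6%, 63.5%, 43.4% and 44.9% within 500 bp. It became 37.1%, 30.6%, 16.7%, 53.9%, 30.1% and 32.1% in the upper part of each list, and 31.2%, 22.8%, 11.4%, 34.8%, 24.2% and 25.1% with equal numbers. With the lowest score of 15 it became 70.4%, 41.5%, 25.7%, 46.8%, 14.4% and 13.9%. Without regions of the ES cell list, Cdx2 with Arid3a in ES+ became 38.9%. The cause was not tested.

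Overlap between media became 51.7%, 36.0% and 49.6% within 100 bp, 63.3%, 47.3% and 59.7% within 500 bp, 57.3%, 45.6% and 54.1% in the upper part, and 38.5%, 41.0% and 43.3% with equal numbers. With the lowest score of 15 it became 71.2%, 84.8% and 79.7%, and without regions of the ES cell list 43.6% for Arid3a. Overlap of the Arid3a antibody summits of TS cells with Arid3a in ES+ and TS+ became 12.7% and 14.4% within 100 bp and 18.04% and 19.4% within 500 bp. It became 12.1% and 12.1% in the upper part, 6.04% and 7.66% with equal numbers, and 25.7% and 6.05% with the lowest score of 15. The cause was not tested.

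Summits inside ES cell peaks became 72.1%, 54.0%, 78.1%, 72.8%, 70.8% and 79.7% within 250 bp of a peak, and 70.8%, 54.8%, 79.6%, 70.1%, 68.9% and 81.8% in the upper part. With the lowest score of 15 they became 74.8% (Cdx2 in ES+), 79.1% (Gata3 in ES+), 73.1%, 80.02% and 88.4%. At that score the excess at bound TS-only regions became 49.3 points (Gata3 in ES+), 50.5 (Cdx2 in TS+) and 82.1 (Arid3a in TS+), and 28.3 for Gata3 in TS+ with an interval of -2.49 to 59.1 that includes 0. These last 3 rest on 11, 20 and 9 bound regions. The cause was not tested.

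Comparisons of gene lists, overexpressed genes, motifs at summits and genomic distribution were not run, for lack of RNA-seq files and of a reference of the build used. ATAC-seq depth of 38056559 to 51977223 tags limits which weak peaks are listed, and a region without a peak in a list was not shown to be closed. ChIP-seq depth is unknown, so the lengths of those lists cannot be set against it.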

Other observations

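All tests in this part were chosen after the result was seen.

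TS-only regions that carry Arid3a in TS cells were gained less often than the rest. Of the 2795 TS-only regions with an Arid3a antibody summit in TS cells, 27.0% (25.4 to 28.7) had a peak in at least 1 factor line, against 32.2% (31.3 to 33.1) of those without. The difference was -5.17 percentage points (-7.06 to -3.28), and it was below 0 in each of the 6 lines, from 17.6% against 20.7% in the Cdx2 line in ES+ to 4.19% against 5.28% in the Gata3 line in TS+. It shrank with the TS score: 21.7% against 33.1% in the weakest of 3 groups by score, and 28.2% against 30.6% in the strongest. In the middle group the Gata3 line in TS+ went the other way, with 5.41% against 4.94%. Chromosome 13 between 65 and 68 Mb held summits of every list. Of Arid3a in ES+ it held 103 (0.529% of the list), of Arid3a in TS+ 55 (0.345%), of Cdx2 50 (0.361%) in ES+ and 20 (0.372%) in TS+, and of Gata3 38 (0.210%) and 30 (0.266%). Of the Arid3a antibody list of TS cells it held 35 (0.297%). The ES cell list that the deposited name calls a mock had 5 there, the highest share at 1.10%, so background at these sites was not ruled out. Gata3 summits were densest on chromosome 10 from 80 Mb in both media, with 66 in ES+ and 37 in TS+ in that Mb.

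Chromosome 1 held a larger share of peaks in ES cells than in TS cells. Weak peaks near the threshold are argued against: among the 10000 highest peaks of each list the ES over TS ratio of its share was 1.54, against 1.26 for the highest other autosome. Chromosome X was left out of that comparison, and its ratio among the same peaks lay just below that of chromosome 1. Among these peaks the ratio thus sets chromosome 1 apart from the other autosomes but not from chromosome X. A few dense parts of chromosome 1 are argued against, as 90% of its 10 Mb bins had an ES over TS peak ratio above the median bin of the other autosomes. A trend with the density of regions is argued against, since the median pileup rank over shared regions lay 18.2 points beyond the trend of the other autosomes, whose largest departure was 4.98. A different number of chromosome 1 copies in ES-derived and TS cells stays open. The median pileup rank of chromosome 1 over shared regions was 17.8 points higher in ES cells than in TS cells, against 10.2 for the highest other autosome, chromosome 14, and 12.2 for chromosome X. In the 6 lines the rank of chromosome 1 was 11.4 to 15.9 points higher, but each of these differences is taken from the same TS cell list, so they are not independent. Chromosome 11 departed further in size in all 6 lines, from -19.8 to -16.04 points, and in the Arid3a line in TS+ chromosome X, at 12.5, exceeded chromosome 1 at 11.4, with chromosome 14 at 11.2. Copy number itself was not measured, and a difference in chromatin between the cell types stays untested.

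Regions with a peak in all 6 factor lines but not in ES cells were often TS cell peaks. With equal numbers of peaks the share was 57.1% (53.4 to 60.8) of 704 regions, and the highest share among regions missing from 1 line alone was 44.8% (39.6 to 50.1), for the Cdx2 line in ES+. With all peaks it was 28.3% (24.6 to 32.2) of 555 regions, and the interval of the 78 regions missing from the Cdx2 line in ES+ alone reached 26.8%. The rule of the test was an interval above those of all other sets, with all peaks and with equal numbers. It was not met with all peaks. A gain of TS regions shared by all lines was thus not separated from what any list that alone misses a region would show. Overlapping intervals do not show that the shares are alike: that of the 78 regions was 16.7%. Low sensitivity of the ES cell library stays open as well: 704 regions were missing from ES cells alone, against 364 to 643 for 5 of the lines and 1673 for the Gata3 line in TS+. No ATAC-seq library of a line without a factor was available, so effects common to making the lines were not tested.

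The medium separated 4524 regions between the 3 ES+ and the 3 TS+ lists (3903 and 621), and the highest count among the other splits of the 6 lists was 2443. There are 10 such splits, of which 1, the real one, separated as many regions, and they are too few for a share under 0.05. With equal numbers of peaks the counts were 2745 and 483.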
